A study of Homo sapiens with 51 samples.

How the data were processed

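RNA was measured by sequencing in 51 libraries of DLD-1 cells, a human colorectal adenocarcinoma line, that fall into 17 groups of 3 libraries. In each of 5 derived lines one nucleoporin of the Y-complex (NUP107, NUP133, NUP160, NUP85 or NUP96) carries an auxin-inducible degron fused to NeonGreen, so that auxin directs the tagged protein to the proteasome. Per the labels' protocols, total RNA was extracted on RNeasy columns and libraries were made with a TruSeq total RNA kit. The groups, times and the auxin concentration of 1 mM were taken from the sample titles and treatment protocols in the labels.

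The authors deposited one table of gene counts per library, whole numbers with no normalisation, over 58051 gene identifiers. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.6.1 and featureCounts 1.6.3 were used with the GRCh38 build; the notes as used here give neither their settings nor their order. Whether the counting used strand is not given in the sources used here, so it is open whether reads of a gene and its antisense partner were separated. Overlapping features received the same reads in some places: RN7SL1 and AL139099.4 have identical totals of 20599454 counts. Gene symbols and GRCh38 coordinates were taken from GENCODE release 29, which named 57447 identifiers; the other 604 held at most 0.296% of the counts of any library and kept their identifiers.

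The libraries of the NUP160 line had been counted on a somewhat different set of features. Of the genes tested, 111 had no count in that line and counts in every other line, against 3 to 31 genes for the other lines taken in turn. Mitochondrial genes had counts in the NUP160 libraries. Differences between treated and untreated libraries of one line are not touched by this if all libraries of the line were counted alike, which was not checked. NUP160 untreated replicate 3 had counts for 40632 genes, against at most 33018 in any other library. An alternative restricted to genes counted in every line was run for the comparisons between lines.

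Total counts ran from 22885113 to 44238272 per library, with a median of 28054671, except for NUP96 untreated replicate 2 with 5810667. At this depth and spread the standard error of a log2 fold change, as the median over genes, lay between 0.235 and 0.242 in the 10 comparisons of auxin with no drug. The fit estimated each gene's spread over all 17 groups together, so these values do not show how the lines differ in spread. No pair of libraries held identical values. No label says that replicates were separate cultures, so p-values measure a spread between libraries, pooled over the 17 groups, which may be technical in part.

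Counts were analysed in R 4.3.3. Genes with low counts were removed with filterByExpr at a minimum count of 10, which left 22149 genes and removed 35902. Libraries were scaled by the TMM method, and edgeR 4.0.16 fitted one quasi-likelihood model with a mean for each of the 17 groups, which leaves 34 residual degrees of freedom and gave a common dispersion of 0.0319. All fold changes, standard errors and adjusted p-values in the text come from this fit and its quasi-likelihood test, with Benjamini-Hochberg adjustment over the genes tested in each comparison. A gene was called at an adjusted p under 0.05, and "rose" and "fell" are used of called genes. Levels are TMM-normalised counts rescaled to a common library total (CPM), given as mean and SD over the 3 libraries of a group.

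The comparisons were auxin for 10 h and for 4 h against untreated cells in each line, hydroxyurea with and without auxin in the NUP96 line, the difference between the auxin effects with and without hydroxyurea, and the 10 h effect in each line minus the mean effect in the other 4 lines. The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names the 8 genes with the largest rise and the 8 with the largest fall for the 10 h and hydroxyurea comparisons, 4 and 4 at 4 h and 3 and 3 for differences between effects. Such genes had to be called, to have a mean log2 CPM of at least 1, to have CPM ranges that do not overlap between the groups (not required for differences between effects), and to carry a symbol other than a clone, small RNA or pseudogene name. With 3 libraries against 3, ranges fail to overlap by chance in 10% of genes. The rule also names the 5 tagged genes, CYP1A1 and CYP1B1, up to 3 called members of each gene list with the smallest adjusted p, and up to 5 rising and 5 falling genes called in all 5 lines. Some members were left out for length.

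Gene lists, 29 in number, were written for this cell type and these treatments. A list was tested if at least 5 of its members were tested, which 28 met. Lists were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01 between genes, adjusted over the 28 lists of a comparison, and again with the correlation estimated from the residuals. Where a list passes only with the preset correlation, the p from the estimated correlation stands beside it. For each list the number of called members is also given with p-values adjusted over the list alone.

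Replicate numbers were checked for pairing by correlating deviations from the group means between libraries with the same number. They went together in 2 comparisons of the NUP96 line: 10 h auxin against untreated (0.259, 0.347 and 0.283 for the 3 numbers) and hydroxyurea with auxin against hydroxyurea (0.622, 0.244 and 0.464). A fit with the replicate number as a block changed the call of 3 named genes there, NUP107 (log2 fold change 0.50, adjusted p = 0.0288) and NUP133 (0.44, adjusted p = 0.0233) in the first and NUP160 (0.58, adjusted p = 0.0474) in the second, none of them called without the block.

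The model was tested on simulated counts with known changes, in which each gene varied alike in every line. The false calls given here therefore do not measure error where lines or single libraries differ in spread. For the NUP85 line at 10 h, in a simulation over 21690 genes, 36% of genes changed 1.5-fold were recovered, 82% of those changed 2-fold, 98% at 4-fold and 100% at 8-fold, with 4 false calls among 162. For the NUP160 effect minus that of the other lines, over 21726 genes, the shares were 32%, 68%, 98% and 100%, with 7 false calls among 156.

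Each result was recomputed with DESeq2 size factors, without the 20 most abundant genes, without the low-count filter, with DESeq2 1.42.0, with a minimum of 2-fold change, with the libraries of the compared lines alone, with a replicate block, and without each library in turn. Alternatives chosen after seeing the data were a block over only the paired groups, leaving out NUP96 untreated replicate 2 and NUP160 untreated replicate 3 together, only the genes counted in every line, and leaving NUP96 untreated replicate 2 out of the exon analysis under hydroxyurea. The analysis by number of exons was also chosen after seeing the data. Exon number, transcript length and GC content came from the annotation for 14661 of 14669 protein-coding genes tested, 99.9% of them. Of those 14661 genes, 65 histone genes were then left out. Results for 5 named genes are withheld for evaluation and not reported here, and 1 of them was left out of the flagged results.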

Results

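Gene expression was measured by RNA sequencing in 5 lines of DLD-1 cells, a human colorectal adenocarcinoma line, each carrying an auxin-inducible degron fused to the green protein NeonGreen on a different subunit of the Y-complex. The Y-complex, also called the NUP107-NUP160 complex, is the scaffold that forms the outer rings of the nuclear pore. The tagged subunits were NUP107, NUP133, NUP160, NUP85 and NUP96, the last encoded by NUP98. Every line was sampled untreated, after 4 h and after 10 h of auxin at 1 mM. The NUP96 line was also sampled after 10 h of hydroxyurea, an inhibitor of ribonucleotide reductase that stalls DNA replication, alone and together with auxin. This gave 17 groups of 3 libraries, and every mean and SD below rests on n = 3 libraries per group. Each SE is for groups of 3 libraries too, but uses a spread estimated over all 17 groups together. It therefore does not show the spread of the compared libraries themselves. All but 1 of the libraries held between 22885113 and 44238272 counts, and NUP96 untreated replicate 2 held 5810667 and had counts for 22666 genes. The other libraries had counts for 27877 to 33018 genes, except NUP160 untreated replicate 3, which had counts for 40632. Untagged cells treated with auxin were not analysed here.

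The degron acts on protein, and the mRNAs of the tagged genes were measured first. NUP107 mRNA (chromosome 12, 68686734 to 68745809, GRCh38) stood at 65.9 ± 2.77 CPM (mean ± SD) in its own untreated line, 70.2 ± 2.05 after 4 h and 66.1 ± 4.77 after 10 h of auxin. NUP85 mRNA (chromosome 17, 75205659 to 75235758) stood at 27.5 ± 3.61 CPM in its own untreated line and at 27.0 CPM after 10 h. Both genes had higher means in the 4 untreated lines in which they were not tagged. NUP133 mRNA (chromosome 1, 229440260 to 229508341) stood at 99.0 ± 14.7 CPM untreated and 103 CPM after 10 h, and NUP160 mRNA (chromosome 11, 47778087 to 47848555) at 76.6 ± 30.5 and 88.5 CPM. NUP98 mRNA (chromosome 11, 3671083 to 3797792) rose in the NUP96 line after 10 h (log2 fold change 0.50, adjusted p = 0.018). Without NUP96 untreated replicate 2 that change was 0.18 (adjusted p = 0.226).

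At 4 h, the first time sampled, the changes common to all lines included targets of the aryl hydrocarbon receptor, a transcription factor activated by indoles and other planar ligands. CYP1A1 (ENSG00000140465, chromosome 15, 74719542 to 74725610), a cytochrome P450 and the receptor's best known target, rose at 4 h in every line. Its level went from 0.566 ± 0.0658 to 65.4 ± 3.06 CPM in the NUP107 line and from 4.64 ± 2.71 to 222 ± 64.1 CPM in the NUP133 line. In the NUP160 line it went from 6.02 ± 5.2 to 208 ± 11.7 CPM, in the NUP85 line from 2.89 ± 0.399 to 130 ± 21.7 CPM and in the NUP96 line from 5.67 ± 2.6 to 238 ± 3.23 CPM. The log2 fold changes were 6.84, 5.59, 5.10, 5.49 and 5.49 in the same order. The NUP160 value was 6.02 without its untreated replicate 1. By 10 h CYP1A1 stood 3.73 above untreated on the log2 scale in the NUP107 line, 2.54 in the NUP160 line and 2.13 in the NUP96 line. The 10 h values were 1.85 in the NUP133 line and 1.52 in the NUP85 line, the latter not called (adjusted p = 0.248). AHRR, the repressor of the receptor, rose at 4 h in all 5 lines by 0.59 to 1.02 on the log2 scale, but its call rested on single libraries in the lines with the smallest rises. It ended in the NUP85 line without untreated replicate 1 (adjusted p = 0.0981), untreated replicate 2 (0.0651) or 4 h replicate 1 (0.0572), and in the NUP133 line without untreated replicate 2 (0.334), untreated replicate 3 (0.0744), 4 h replicate 1 (0.215) or 4 h replicate 2 (0.111). TIPARP, a mono-ADP-ribosyltransferase that restrains the receptor, rose at 4 h in the NUP107 line (2.05 ± 0.2, log2 fold change ± SE), the NUP160 line (1.51) and the NUP96 line (1.52). It rose by 1.007 in the NUP133 line too (adjusted p = 0.018), a call lost without any 1 of the 6 libraries (0.0587 to 0.291), and its value in the NUP85 line was 0.87 (adjusted p = 0.163).

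Of 11 receptor targets tested, the number that rose at 4 h was 5 in the NUP107 line (6 adjusted over the list alone), 4 in the NUP133 line (7), 5 in the NUP160 line (9), 3 in the NUP85 line (5) and 6 in the NUP96 line (8), and none fell. The list's median log2 fold changes were 0.52, 0.53, 0.59, 0.69 and 0.79 in the same order. The list passed camera's test in every line with the estimated correlation too (adjusted p = 7.68e-09, 2.03e-11, 2.89e-11, 3.64e-13 and 0.000103). The CYP1A1 rise in the NUP107 line was not separable from the mean rise in the other 4 lines (difference 1.43 on the log2 scale, adjusted p = 0.407), in a test chosen after the values were seen.

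**Figure D1:**
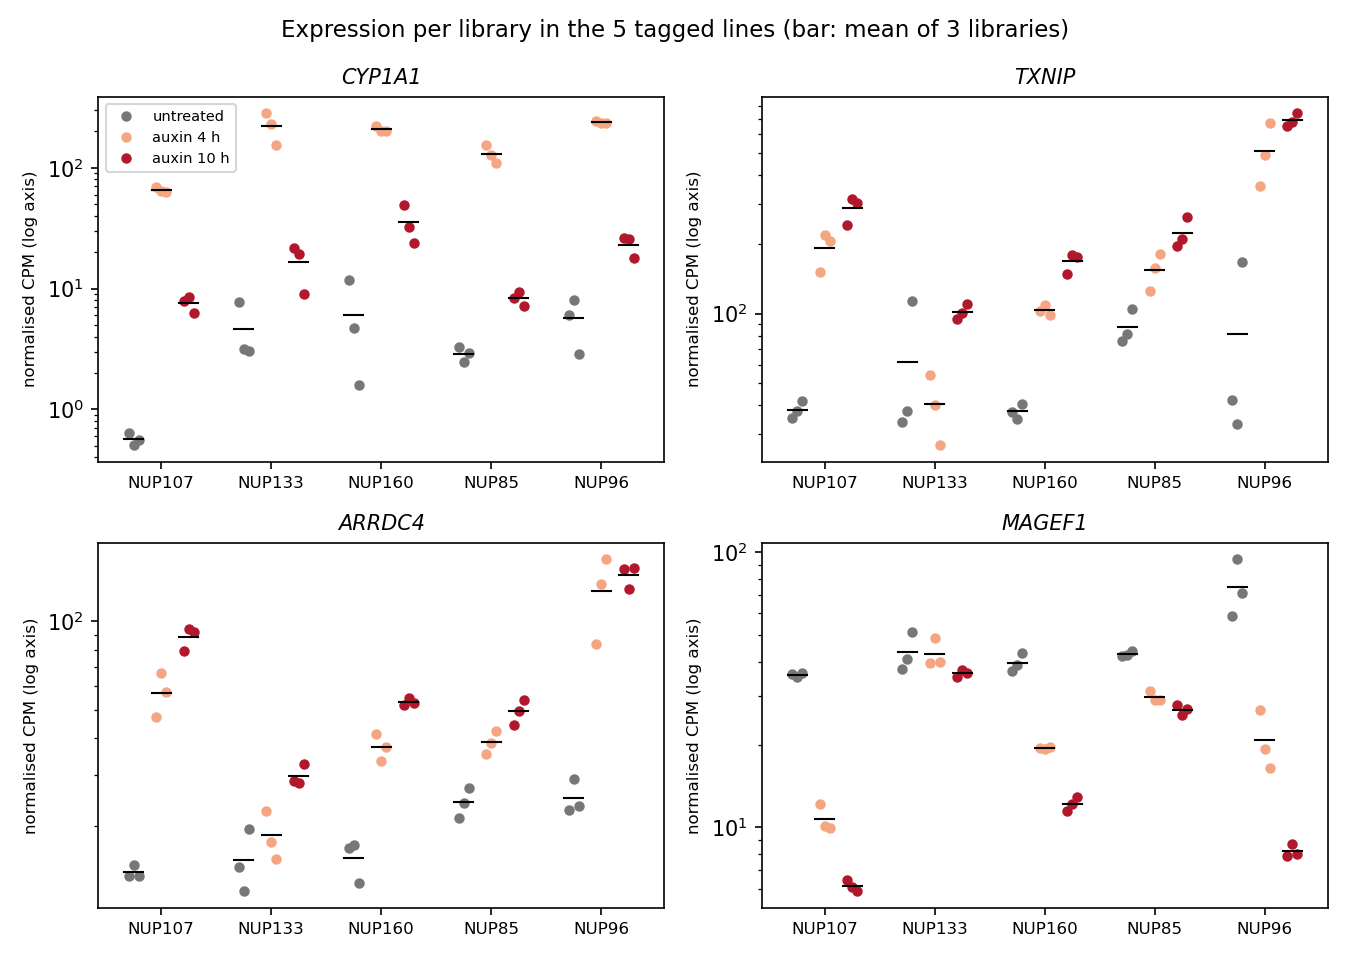
Normalised CPM on a log axis for CYP1A1, TXNIP, ARRDC4 and MAGEF1, one point per library and one column per line; grey marks untreated libraries, orange 4 h and red 10 h of auxin, and the bar is the mean of 3. At 4 h the lowest CYP1A1 library of each line lies at least 17 times above the highest untreated library of that line.

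Beyond this list the lines differed widely in how many genes auxin changed. At 10 h, 7038 genes were called in the NUP96 line, 6989 in the NUP107 line and 1698 in the NUP160 line, against 11 in the NUP85 line and 9 in the NUP133 line. At 4 h the counts were 3079, 994, 149, 4 and 9 in the same order. The order of the lines changed in fits of each line's own libraries, with 2235, 12204 and 2814 genes at 10 h in the NUP96, NUP107 and NUP160 lines and 162, 4649 and 243 at 4 h. The NUP85 line had 129 at 10 h and 79 at 4 h in such a fit. Without NUP96 untreated replicate 2 the NUP96 count at 4 h was 944. The tests of the differences between lines are given further on.

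**Figure D2:**
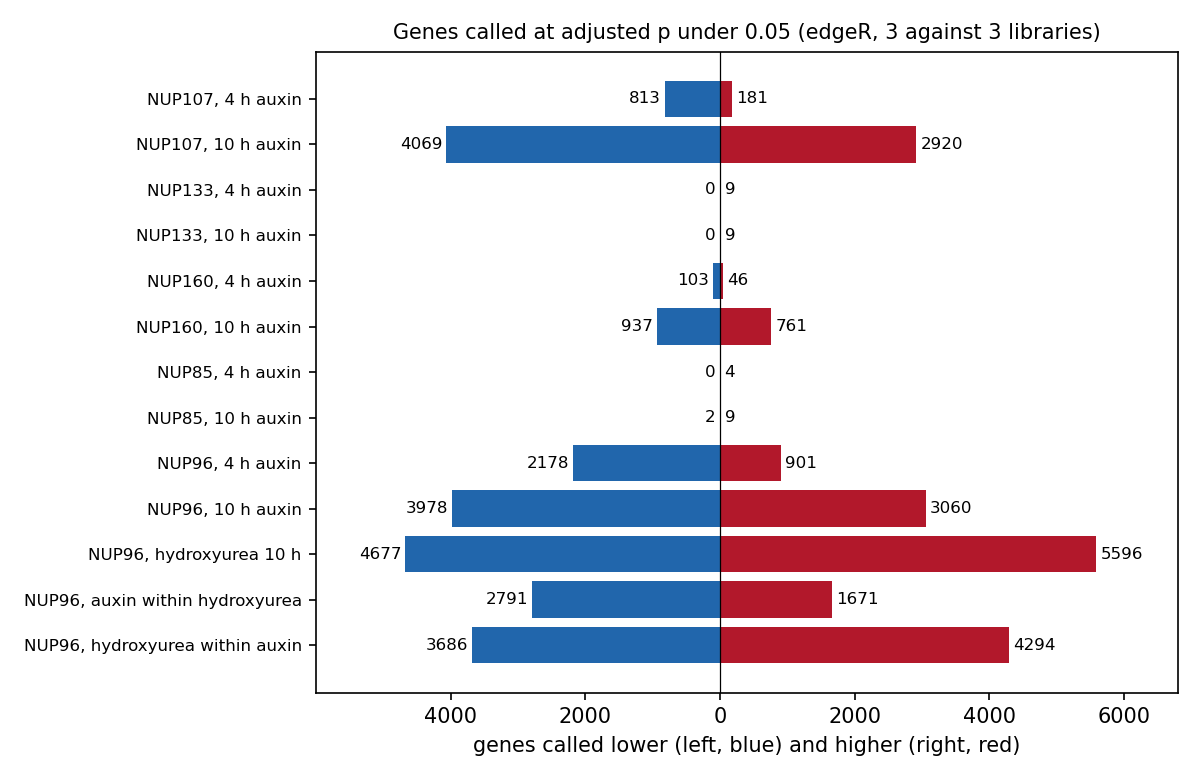
Number of genes called lower (blue, to the left of 0) and higher (red, to the right) at an adjusted p under 0.05 in 13 comparisons, with edgeR's quasi-likelihood test over 22149 genes. Of the auxin comparisons without hydroxyurea, the NUP96 and NUP107 lines at 10 h have the longest bars, with 7038 and 6989 genes.

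In the NUP107 line, 10 h of auxin raised 2920 genes and lowered 4069. Among the largest rises were transcription factors of the immediate early response. FOS rose from 5.83 ± 0.853 to 63.1 ± 3.48 CPM (log2 fold change 3.44 ± 0.268, adjusted p = 1.88e-13), JUN from 6.08 ± 0.278 to 66.1 ± 4.31 CPM (3.44 ± 0.592, adjusted p = 1.2e-05) and EGR1 from 37.5 ± 4.73 to 240 ± 14.7 CPM (2.68 ± 0.367, adjusted p = 1.82e-07). GDF15, a secreted stress cytokine, rose from 73.9 ± 1.23 to 521 ± 21.1 CPM. TXNIP, the thioredoxin-interacting protein, rose from 38.3 ± 3.22 to 287 ± 38.3 CPM, and its relative ARRDC4 rose by 2.67 on the log2 scale (adjusted p = 2.96e-14). HIST1H3PS1, a histone pseudogene that can share reads with histone genes, went from 0.312 to 9.02 CPM. The antisense gene STAM-AS1 rose by 2.69 on the log2 scale, with the limit that strand use in counting is not given in the sources used here.

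The deepest falls in that line included F2R, the thrombin receptor (log2 fold change -3.45 ± 0.271), KLHL23 (46.0 ± 1.6 to 4.33 ± 0.349 CPM, adjusted p = 1.24e-13) and RTL6 (51.1 ± 0.432 to 6.4 ± 0.633 CPM, adjusted p = 5.4e-22). SLC26A2, a sulfate transporter, fell from 38.7 ± 1.5 to 5.14 ± 0.684 CPM. ASCL2, a transcription factor of intestinal stem cells and a WNT target, fell from 74.5 ± 2.95 to 10.3 ± 0.663 CPM (-2.85 ± 0.297, adjusted p = 3.68e-10). TMEM187 (-3.20), TMEM86A (-3.07) and F8A1 (-2.91) fell by similar amounts.

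Of 32 immediate early genes tested in the NUP107 line at 10 h, 21 rose and 4 fell (21 and 5 adjusted over the list alone), with a median log2 fold change of 1.07 (camera adjusted p = 1.02e-09; adjusted p = 0.28 with an estimated correlation). DUSP6 (1.76 ± 0.148), a phosphatase of ERK, and KLF10 (1.99 ± 0.172), a zinc finger transcription factor, were among them. Host genes of small nucleolar RNAs moved one way: 10 of 20 rose and 0 fell (the same adjusted over the list alone), SNHG10 by 1.89, SNHG15 by 1.32 and SNHG19 by 1.22 (median 0.61, adjusted p = 9.46e-05; adjusted p = 0.28 with an estimated correlation). Ribosome biogenesis genes gave 14 rises and 1 fall among 37 (16 and 1 adjusted over the list alone), with NOB1 at 0.97 and GNL2 at 0.77 (camera adjusted p = 0.00252; adjusted p = 0.889 with an estimated correlation). Among 26 mRNA export factors, 8 rose and 2 fell (9 and 3 adjusted over the list alone). The RNA helicases DDX39A (1.71 ± 0.158, adjusted p = 1.64e-11) and DDX39B (0.71) and the export receptor NXF1 (0.88) rose, and the list had an adjusted p of 0.0466 (adjusted p = 0.889 with an estimated correlation). Of 21 NF-kB targets, 6 rose and 0 fell (the same adjusted over the list alone), ICAM1 by 0.99, CXCL2 by 1.78 and CSF2 by 2.33 (adjusted p = 0.0498; adjusted p = 0.889 with an estimated correlation). TGF-beta and mesenchymal genes gave the same counts among 20, with SNAI1 at 1.58, LTBP2 at 1.42 and SMAD7 at 0.72 (adjusted p = 0.0498; adjusted p = 0.708 with an estimated correlation).

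Other lists held called genes but did not pass camera's test. Of 34 HOX genes, which set positional identity, 4 rose and 9 fell (the same adjusted over the list alone), among them HOXB13 (-2.17 ± 0.255), HOXA13 (-1.78) and HOXB9 (-1.60) (camera adjusted p = 0.261). Among 25 genes of the integrated stress response, 2 rose and 9 fell (2 and 10 adjusted over the list alone). CHAC1 (-2.79 ± 0.264), an enzyme that degrades glutathione, and the transcription factors CEBPG (-1.31) and ATF4 (-1.32) fell (list adjusted p = 0.112). Interferon-stimulated genes gave 0 rises and 10 falls among 24 (the same adjusted over the list alone), with STAT2 at -1.19 and OAS3 at -0.96 (list adjusted p = 0.0776). Of 21 WNT targets in colon epithelium, 4 rose and 8 fell (the same adjusted over the list alone), SP5 (-1.50) and NKD1 (-1.37) besides ASCL2 (list adjusted p = 0.525). Of 43 S phase and E2F genes, 8 rose and 13 fell (8 and 14 adjusted over the list alone), including the flap endonuclease FEN1 (-1.39 ± 0.118) and BRCA1 (-1.91 ± 0.223) (list adjusted p = 0.644). Among 27 p53 targets, 5 rose, GDF15 among them, and 7 fell (5 and 8 adjusted over the list alone), including XPC (-1.18) and TRIAP1 (-1.82) (list adjusted p = 0.525). Of 23 nucleoporins outside the Y-complex, NUP153 (1.06) and NUP58 (0.68) were among 4 that rose and AAAS (-0.49) among 2 that fell, the same adjusted over the list alone (list adjusted p = 0.491).

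At 4 h the NUP107 line had 181 genes higher and 813 lower, and the total was 595 without 4 h replicate 2 and 654 without 4 h replicate 3. TXNIP rose from 38.3 to 192 ± 36 CPM (log2 fold change 2.33 ± 0.421, adjusted p = 0.000182) and ARRDC4 from 14 to 57.1 CPM (2.03 ± 0.188, adjusted p = 3.87e-10). FAM43A (-1.99), IRGQ (-1.98 ± 0.199, adjusted p = 1.99e-09), WDCP (-1.97) and FRAT1 (-1.87), a WNT pathway activator, fell the most. Of 32 immediate early genes, 3 rose and 2 fell (6 and 4 adjusted over the list alone), with KLF10 at 0.82, DUSP6 at 0.75 and IER5 at -1.59 (list adjusted p = 0.521). HOX genes gave 0 rises and 4 falls among 34 (the same adjusted over the list alone), HOXA13 by -1.30, HOXB9 by -0.77 and HOXA11 by -0.72 (median -0.34, adjusted p = 0.00092; adjusted p = 0.891 with an estimated correlation). 

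In the NUP96 line, 10 h of auxin raised 3060 genes and lowered 3978. TXNIP rose from 81.3 ± 75.6 to 691 ± 47 CPM (log2 fold change 3.07 ± 0.432, adjusted p = 5.05e-07; 4.19 without untreated replicate 3). ARRDC4 rose from 25 ± 3.42 to 144 ± 12.8 CPM (2.54 ± 0.191, adjusted p = 1.9e-13) and KLF11, a zinc finger repressor, from 11.7 to 46.0 CPM (1.95 ± 0.281, adjusted p = 8.8e-07). FBN1, the extracellular matrix protein fibrillin, rose by 2.07 ± 0.311 and the collagen receptor DDR2 by 2.01 ± 0.307 on the log2 scale. MAGEF1, a gene with 1 exon on chromosome 3 (184710367 to 184712002), fell from 74.7 ± 18.1 to 8.21 ± 0.452 CPM (-3.18 ± 0.176, adjusted p = 2.19e-17). MFSD6L (-3.11 ± 0.276), IRGQ (-3.07 ± 0.206) and EID2 (-3.03 ± 0.249) fell by like amounts. RNF26 (-3.27), AP5B1 (-3.27), FOXQ1 (-3.24) and SOX12 (-3.17) had deeper values, which became -1.98, -2.22, -2.28 and -2.08 without untreated replicate 2, the shallow library. A fit of this line's own libraries called 2235 genes. With a replicate block over the 2 groups, whose numbers paired, the majority turned, to 4408 higher and 3975 lower.

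Several lists passed camera's test in the NUP96 line at 10 h with the preset correlation only. Of 41 G2/M genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone), including the kinase TTK (1.27) and the spindle midzone protein PRC1 (0.62) (median 0.42, adjusted p = 0.000847; adjusted p = 0.934 with an estimated correlation). Among 30 nuclear transport receptors, 11 rose and 1 fell (15 and 1 adjusted over the list alone), with the importins KPNA5 at 1.21 and KPNA4 at 0.81 (adjusted p = 0.00361; adjusted p = 0.934 with an estimated correlation). Of 26 mRNA export factors, 9 rose and 0 fell (the same adjusted over the list alone), DDX39A by 1.09 and DDX39B by 0.75 among them (adjusted p = 0.00438; adjusted p = 0.934 with an estimated correlation). Of 23 nucleoporins outside the Y-complex, 7 rose and 2 fell (8 and 3 adjusted over the list alone), including NUP35 (1.22) and NUP153 (0.77) (adjusted p = 0.0399; adjusted p = 0.934 with an estimated correlation). Ribosome biogenesis genes gave 13 rises and 0 falls among 37 (16 and 0 adjusted over the list alone; adjusted p = 0.00361, and adjusted p = 0.94 with an estimated correlation). In the fit of this line's own libraries TTK (adjusted p = 0.115), PRC1 (0.085), KPNA5 (0.0619) and NUP35 (0.0611) were not called. HOX genes gave 0 rises and 9 falls among 34 (the same adjusted over the list alone), HOXB9 by -2.27 ± 0.195, HOXB13 by -1.55 and HOXB7 by -1.25 (adjusted p = 0.0287; adjusted p = 0.934 with an estimated correlation). Interferon-stimulated genes gave 0 rises and 8 falls among 24 (the same adjusted over the list alone; list adjusted p = 0.261). Of 32 immediate early genes, 6 rose and 5 fell (6 and 7 adjusted over the list alone), with KLF10 at 1.77 and DUSP6 at 1.16 (list adjusted p = 0.551).

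At 4 h the NUP96 line had 901 genes higher and 2178 lower, and 944 in all without untreated replicate 2. Other single libraries moved the total by over 1.5 times as well, to 1568 and 1763 without 4 h replicates 2 and 3 and to 6230 and 5340 without untreated replicates 1 and 3. ARRDC4 rose from 25 to 127 ± 39.8 CPM (log2 fold change 2.35 ± 0.19, adjusted p = 1.81e-11), and TXNIP by 2.62 ± 0.424 (3.76 without untreated replicate 3). The rule's 4 deepest falls rested on untreated replicate 2: without it ZNF703 went from -2.87 to -0.163, SOX12 from -2.87 to -1.77, KLF16 from -2.75 to -0.935 and ZNF865 from -2.75 to -0.63, with ZNF703 and ZNF865 no longer called. Of 32 immediate early genes, 2 rose, KLF10 (1.16) among them, and 12 fell (2 and 13 adjusted over the list alone), with a median of -0.54 (adjusted p = 0.00431; adjusted p = 0.749 with an estimated correlation).

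In the NUP160 line, 10 h of auxin raised 761 genes and lowered 937. With a minimum of 2-fold added the majority turned, to 342 higher and 311 lower. TXNIP rose from 37.6 ± 2.78 to 169 ± 17.3 CPM (log2 fold change 2.17 ± 0.418, adjusted p = 0.000477), ARRDC4 by 1.76 (adjusted p = 2.22e-08), KLF11 from 7.4 to 25.3 CPM (1.77 ± 0.279) and the orphan receptor GPR61 by 2.43 ± 0.272. CYP1A1 rose by 2.54 ± 0.376 (3.46 without untreated replicate 1). MAGEF1 fell from 39.5 ± 3.04 to 12.2 ± 0.717 CPM (-1.69 ± 0.166, adjusted p = 3.56e-09), C1orf216 from 24.9 to 7.69 CPM (-1.70 ± 0.16) and CIPC, a partner of the clock protein CLOCK, by -1.54 ± 0.176. Without single libraries the total count lay between 1001 and 1525, with 1001 without 10 h replicate 2, 1009 without 10 h replicate 3 and 1084 without untreated replicate 2. Mitochondrial ribosomal RNAs fell in edgeR's fit (MT-RNR1 from 500 ± 342 to 26.4 CPM, -4.25; -3.60 without untreated replicate 2), but DESeq2 gave adjusted p = 0.876.

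Of 32 immediate early genes in the NUP160 line at 10 h, 9 rose and 0 fell (14 and 0 adjusted over the list alone), including CYR61 (1.6 ± 0.324), CTGF (1.66 ± 0.344) and FOS (1.22 ± 0.247) (median 0.64, adjusted p = 1.27e-08; adjusted p = 0.386 with an estimated correlation). Aryl hydrocarbon receptor targets gave 4 rises and 0 falls among 11 (6 and 0 adjusted over the list alone; adjusted p = 9.86e-06, and adjusted p = 0.00172 with an estimated correlation). Of 55 replication-dependent histone genes, 2 rose and 8 fell (4 and 11 adjusted over the list alone), with HIST1H1E at -1.13, HIST1H4I at -1.03 and HIST1H1B at -0.98 (list adjusted p = 0.0601). HOX genes gave 0 rises and 3 falls among 34 (the same adjusted over the list alone), HOXB9 by -1.04 and HOXB13 by -1.01 among them (list adjusted p = 0.422). At 4 h in this line 46 genes rose and 103 fell. Of those, CYP1B1 rose by 1.63 ± 0.28, and SDHAF1, an assembly factor of succinate dehydrogenase, fell by 1.27 on the log2 scale (adjusted p = 0.00057). The 4 h total was 67, 69 and 81 without each 4 h library and 89 and 72 without untreated replicates 2 and 3.

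In the NUP133 and NUP85 lines few genes were called. At 10 h in the NUP133 line the 9 called genes all rose, among them CYP1A1 (log2 fold change 1.85 ± 0.375, adjusted p = 0.0408) and ARRDC4 (0.95, adjusted p = 0.0322). CYP1A1 lost its call without 10 h replicate 1 (adjusted p = 0.354) or 2 (0.158) or untreated replicate 2 (0.277) or 3 (0.236), and ARRDC4 without any 1 of the 10 h libraries (0.172, 0.085 and 0.143) or untreated replicate 1 (0.163) or 2 (0.241). In a fit of the NUP133 libraries alone edgeR called 0 genes, with 620 at an unadjusted p under 0.05, and DESeq2 over all libraries called 21. Leaving out any 1 of the 6 libraries left 1 to 5 genes. At 10 h in the NUP85 line 9 genes rose, ARRDC4 from 24.2 ± 2.83 to 49.4 ± 4.82 CPM (1.03 ± 0.182, adjusted p = 0.00704), and 2 fell, UBQLN2 (17.8 ± 1.7 to 9.18 ± 0.607 CPM) and AC025257.1, the last named after its value was seen. ARRDC4 lost its call there without 10 h replicate 2 (adjusted p = 0.0518), 10 h replicate 3 (0.0643), untreated replicate 1 (0.142) or untreated replicate 2 (0.11), and UBQLN2 without any 1 of the 6 libraries (0.0797 to 0.296). The count was 4 and 2 without 10 h replicates 1 and 2, and 2, 1 and 3 without untreated replicates 1, 2 and 3. At 4 h, CYP1A1 was called in both lines under every library left out. The NUP85 line's 4 genes were CYP1A1, CYP1B1, AHRR and STMND1, the last named after its value was seen. CYP1B1 lost its call there without 4 h replicate 1 (adjusted p = 0.0549) or any 1 of the untreated libraries (0.155, 0.0651 and 0.05), AHRR as given above, and the count was 2 without 4 h replicate 1, 1 without untreated replicate 1 or 2 and 2 without untreated replicate 3. The NUP133 line's 9 genes at 4 h became 1 to 22, with 5 without 4 h replicate 1, 22 without untreated replicate 1 and 1 without untreated replicate 2 or 3.

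Whole-list tests still found shifts in these lines. Immediate early genes at 10 h had a median log2 fold change of 0.26 in the NUP133 line with 0 of 32 called (5 higher adjusted over the list alone; adjusted p = 4.29e-10, and adjusted p = 0.251 with an estimated correlation). In the NUP85 line the median was 0.31 with 0 called (3 higher adjusted over the list alone; adjusted p = 2.01e-11, and adjusted p = 0.171 with an estimated correlation). Aryl hydrocarbon receptor targets at 10 h passed with the estimated correlation as well, at adjusted p = 0.0121 in the NUP133 line and adjusted p = 0.00906 in the NUP85 line, with 1 and 0 of 11 called (1 and 1 adjusted over the list alone).

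Changes in the lines with many calls went largely the same way. At 10 h, 1456 genes rose and 2293 fell in both the NUP107 and the NUP96 line, where independent lists of the same lengths would share 403 and 731, and 55 went in opposite directions. The log2 fold changes correlated across genes, which are not independent replicates, with r = 0.616. For NUP107 and NUP160, 563 genes rose in both (100 for independent lists), 827 fell in both (172) and 6 were opposite. For NUP160 and NUP96 the numbers were 490 (105), 816 (168) and 2. These pairs share no libraries. ARRDC4 (chromosome 15, 97960698 to 97973838), an arrestin domain protein, and HIST1H3PS1 were the 2 genes that rose in all 5 lines at 10 h. Without single libraries 1 to 3 genes were shared, and a fit of each line alone gave 0 because the NUP133 line then had none. At 4 h the genes called in all 5 lines were AHRR, CYP1B1, CYP1A1 and STMND1. The NUP133 line kept only CYP1A1 at 4 h without its untreated replicate 2 or 3. The NUP85 line kept only CYP1A1 without its untreated replicate 1 or 2. In each of these cases AHRR, CYP1B1 and STMND1 were no longer shared.

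Genes with few exons lay lower than genes with many after auxin in 4 of the lines, by much less in the NUP85 line than in the NUP107, NUP160 and NUP96 lines. This grouping was chosen after seeing the data. Among 328 protein-coding genes with 1 exon, histone genes left out, 161 fell in the NUP107 line at 10 h (49.1%), 77 in the NUP160 line (23.5%) and 196 in the NUP96 line (59.8%). Among 7643 genes with 9 or more exons the shares were 14.9%, 2.2% and 13.1%. Median log2 fold changes of the genes with 1 exon were -0.755, -0.383 and -1.161, and those of genes with 9 or more exons 0.014, 0.040 and 0.137. In the NUP133 and NUP85 lines the medians of genes with 1 exon were -0.037 and -0.109. Camera with the estimated correlation gave an adjusted p of 0.00196 for NUP107, 0.00196 for NUP160, 1.08e-06 for NUP96, 0.0181 for NUP85 and 0.835 for NUP133 at 10 h, and 0.00166 for NUP85 at 4 h. Each gene with 1 exon was also set against a gene with several exons matched on GC content, length and mean expression. That difference was -0.692 ± 0.132 (SD of the 3 treated libraries) for NUP107, -0.378 ± 0.056 for NUP160, -1.140 ± 0.025 for NUP96, -0.093 ± 0.021 for NUP85 and 0.031 ± 0.027 for NUP133. Each treated library was set against the same mean of the untreated ones, so these SDs leave out the spread of the untreated libraries. Without NUP96 untreated replicate 2 the NUP96 value at 10 h was -0.928 ± 0.076. At 4 h the matched difference was -0.689 ± 0.019, -0.390 ± 0.018, -0.833 ± 0.035, -0.153 ± 0.049 and 0.051 ± 0.010 in the same order of lines. Hydroxyurea alone, with no auxin, gave -0.346 ± 0.031 in the NUP96 line, near the NUP160 value with auxin, and -0.303 ± 0.026 without untreated replicate 2 (camera adjusted p = 0.12 with an estimated correlation over all libraries). Auxin added to hydroxyurea gave -0.780 ± 0.1 (adjusted p = 1.76e-05 with an estimated correlation), and 153 of the 328 genes with 1 exon fell (46.6%). Of the genes named above for the deepest falls at 10 h in the NUP107 and NUP96 lines, F8A1, MAGEF1, MFSD6L, EID2, RNF26, FOXQ1 and SOX12 have 1 exon and F2R, TMEM187, RTL6, ASCL2 and AP5B1 have 2. TMEM86A, SLC26A2 and IRGQ have 3 and KLHL23 has 4, and JUN, which rose in the NUP107 line, has 1.

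**Figure D3:**
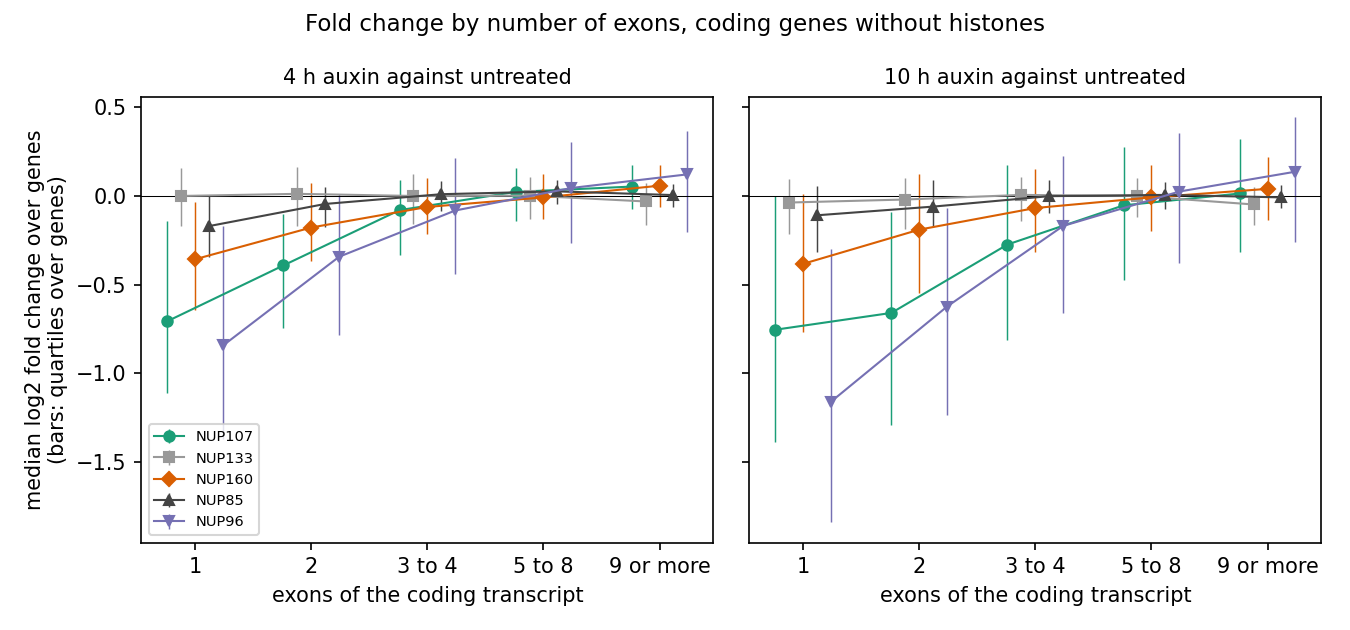
Median log2 fold change of protein-coding genes after 4 h (left) and 10 h (right) of auxin against the number of exons, one line per cell line, with bars from the lower to the upper quartile over genes. At 10 h the median of genes with 1 exon lies at -1.161 in the NUP96 line and at -0.037 in the NUP133 line.

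Whether a line's 10 h response differed from the mean response of the other 4 was tested directly. For NUP160 that mean takes in NUP107 and NUP96 with many calls and NUP133 and NUP85 with few, so a response between these can lie near it. Higher and lower here are relative to the mean, and a gene can be higher because it fell in other lines. The response differed for 2847 genes in the NUP107 line, with GDF15 (difference of log2 fold changes 2.56 ± 0.444), FOS (2.23) and EGR1 (2.21) above the other lines and KLHL23 (-2.48 ± 0.276), TMEM187 (-2.45) and CHAC1 (-2.43) below. In the NUP133 line it differed for 934 genes, 743 of them higher, led by the long noncoding RNA NORAD (1.8 ± 0.259), MAGEF1 (1.77 ± 0.182) and TTC30A (1.73). In the NUP85 line it differed for 556 genes, 488 of them higher, led by F2R (1.68 ± 0.255), GPRIN2 (1.55) and the calcium channel gene ORAI3 (1.53). In the NUP96 line it differed for 1987 genes, 498 higher and 1489 lower. ANKRD36 (1.45) was above the other lines, and CTXN1 was below at -3.38 but at -0.215 without NUP96 untreated replicate 2 (adjusted p = 0.764). In the NUP160 line it differed for 4 genes, among them ZKSCAN2, RTL6 and DCAF4L1, the last named after its value was seen. That count was 18 without NUP96 untreated replicate 2 and 7 without NUP96 untreated replicate 1. None was called without any 1 of the NUP160 10 h libraries, where ZKSCAN2 and RTL6 had adjusted p between 0.0927 and 0.374. The count stayed at 4 or 5 without NUP133 untreated replicate 2, NUP160 untreated replicate 1 or NUP96 untreated replicate 3, and lay between 0 and 2 without any other untreated or 10 h library. Of the other counts, NUP133 moved to 527 and 587 without its untreated replicates 2 and 1 and to 1480 without NUP96 untreated replicate 2, NUP85 to between 279 and 330 without any 1 of its own 6 libraries and to 1012 without NUP96 untreated replicate 2, and NUP96 to 1002 and 1178 without its 10 h replicates 1 and 3 and to 5161, 790 and 3733 without its untreated replicates 1, 2 and 3.

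Hydroxyurea for 10 h changed 10273 genes in the NUP96 line, 5596 up and 4677 down. The majority turned without the 20 most abundant genes, to 4914 up and 5243 down, and in the fit of this line's own libraries, to 2844 up and 2873 down. Replication-dependent histone mRNAs fell, 54 of the 55 tested. HIST1H1D, a linker histone (chromosome 6, 26234268 to 26234933), fell from 231 ± 64.6 to 12.6 ± 5.69 CPM (log2 fold change -4.20 ± 0.251, adjusted p = 8.46e-17), and HIST1H2BM fell from 20.1 to 0.236 CPM (-6.41 ± 0.47; -7.05 without hydroxyurea replicate 1). Among the largest rises, the neutrophil chemokine CXCL8 rose from 0.595 ± 0.634 to 99.9 ± 83.1 CPM (7.17 ± 1.018, adjusted p = 2.96e-07; 8.44 without untreated replicate 3 and 6.56 without untreated replicate 1) and TM4SF19 by 5.38 ± 0.581. Hydroxyurea replicate 1 stood apart, with CXCL8 at 3.982 CPM against 145.7 and 149.9 in replicates 2 and 3. CDKN1A, the p53-induced inhibitor of cyclin-dependent kinases on chromosome 6 (36676460 to 36687339), rose by 3.45 ± 0.361 (adjusted p = 6.22e-10). CTXN1 (-4.38) and ASCL2 (-4.28) fell too, with values of -1.22 and -3.42 without untreated replicate 2.

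Of 55 replication-dependent histone genes tested, 54 fell with hydroxyurea and 0 rose (the same adjusted over the list alone), with a median of -2.45 (adjusted p = 2.69e-84; adjusted p = 0.00601 with an estimated correlation). Histone genes are near-identical in sequence, and reads can be split among them. Of 27 p53 targets, 17 rose and 2 fell (the same adjusted over the list alone), including the death receptor TNFRSF10B (1.24) and the kinase PLK3 (1.79) (adjusted p = 0.00169; adjusted p = 0.0433 with an estimated correlation). Of 21 NF-kB targets, 18 rose and 0 fell (the same adjusted over the list alone), CSF2 by 5.04 ± 0.53, CSF1 by 2.32 and ICAM1 by 1.35 (adjusted p = 1.02e-05; adjusted p = 0.369 with an estimated correlation). ER chaperones gave 16 rises among 17 (the same adjusted over the list alone), HSP90B1 by 1.69 ± 0.162, DNAJC3 by 1.92 and DNAJB11 by 1.29 (adjusted p = 2.13e-09; adjusted p = 0.196 with an estimated correlation). Among 25 genes of the integrated stress response, 19 rose and 1 fell (the same adjusted over the list alone), with ATF3 at 4.19 and CHAC1 at 2.02 (adjusted p = 1.38e-05; adjusted p = 0.369 with an estimated correlation). Hydroxyurea replicate 1 differed here too, with ATF3 at 18.04 CPM against 168.8 and 188.2 and ATF4 at 312.8 CPM against 729.1 and 823.1, below untreated replicates 1 and 3 (370.5 and 487.7). Ribosome biogenesis genes gave 0 rises and 21 falls among 37 (0 and 22 adjusted over the list alone), GRWD1 by -1.64 and PES1 by -1.04 (adjusted p = 1.02e-05; adjusted p = 0.648 with an estimated correlation). HOX genes gave 4 rises and 14 falls among 34 (4 and 15 adjusted over the list alone), HOXA10 by -2.19 and HOXB7 by -1.55 (adjusted p = 7.97e-05; adjusted p = 0.342 with an estimated correlation). WNT targets gave 4 rises and 10 falls among 21 (the same adjusted over the list alone), AXIN2 by -1.94 and LEF1 by -1.48 (adjusted p = 0.00443; adjusted p = 0.369 with an estimated correlation).

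S phase and G2/M genes moved both ways with hydroxyurea. Of 43 S phase and E2F genes, 17 rose and 11 fell (the same adjusted over the list alone), with the licensing factor CDC6 (1.41 ± 0.114) and cyclin CCNE2 (1.87) higher and the helicase subunit MCM5 (-1.15) lower (list adjusted p = 0.711). Of 41 G2/M genes, 4 rose and 11 fell (the same adjusted over the list alone), the mitotic kinase PLK1 by -2.08, the cyclin CCNF by -1.31 and CDC20 by -1.30 (list adjusted p = 0.522). Of 5 blood cell markers tested, which are expressed by another cell type, 3 rose with hydroxyurea, ITGAM by 3.02, CSF1R by 2.22 and CD68 by 2.09 (the same adjusted over the list alone; list adjusted p = 0.307).

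Added to hydroxyurea, auxin changed 4462 genes, 1671 up and 2791 down, against hydroxyurea alone. TXNIP rose from 74.6 ± 41.2 to 910 ± 348 CPM (log2 fold change 3.61 ± 0.442, adjusted p = 3.62e-08), ARRDC4 from 25.1 to 218 ± 34.9 CPM (3.12 ± 0.194, adjusted p = 2.08e-15) and CYP1A1 by 2.23 ± 0.401. MAGEF1 fell from 61.4 to 6.79 CPM (-3.17 ± 0.177, adjusted p = 7.58e-17), IRGQ from 86.1 to 13.8 CPM and SFN, a p53-induced 14-3-3 protein, from 658 ± 329 to 106 ± 43.5 CPM (-2.64 ± 0.251, adjusted p = 1.24e-10). ADM2 (-2.79), RNF26 (-2.77) and C1orf210 (-2.60) fell as well. Genes of the integrated stress response gave 0 rises and 11 falls among 25 (the same adjusted over the list alone), CHAC1 by -1.77, CEBPG by -1.56 and ATF4 by -1.52 (adjusted p = 0.000636; adjusted p = 0.794 with an estimated correlation). Of 27 p53 targets, 0 rose and 8 fell (1 and 8 adjusted over the list alone), TRIAP1 by -1.88 and CDKN1A by -1.61 (list adjusted p = 0.293). Immediate early genes gave 9 rises and 3 falls among 32 (10 and 3 adjusted over the list alone), KLF10 by 1.51, FOS by 1.38 and DUSP6 by 0.84 (adjusted p = 0.00491; adjusted p = 0.794 with an estimated correlation). A fit of this line's own libraries called 1054 genes.

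With auxin present in both groups, hydroxyurea changed 7980 genes, 4294 up and 3686 down. The majority turned to 3695 up and 4276 down without the 20 most abundant genes and to 3569 and 3718 without the low-count filter. It also turned without auxin replicates 1, 2 or 3 (3710 and 3772, 2907 and 2954, 3341 and 3430) or replicate 1 of both treatments (4150 and 4190). A fit of this line's own libraries called 2705 genes, 1411 up and 1294 down. HIST1H1D fell from 286 to 11.7 CPM (log2 fold change -4.60 ± 0.255, adjusted p = 2.25e-17), and 51 of 55 histone genes fell with 0 rises (the same adjusted over the list alone; adjusted p = 2.36e-100, and adjusted p = 0.00183 with an estimated correlation). CSF2 rose from 1.13 to 33.6 CPM (4.92 ± 0.47). NF-kB targets gave 16 rises among 21 (the same adjusted over the list alone), IL1A by 3.83 and TNFAIP3 by 2.23 (adjusted p = 2.99e-07; adjusted p = 0.24 with an estimated correlation). Of 27 p53 targets, 11 rose and 1 fell (12 and 1 adjusted over the list alone), CDKN1A by 3.25 and MDM2 by 1.62 (adjusted p = 0.00165; adjusted p = 0.0639 with an estimated correlation). Of 75 ribosomal protein genes, 0 rose and 56 fell (0 and 63 adjusted over the list alone), RPS15 by -1.50 and RPL8 by -0.91 (median -0.67, adjusted p = 2.9e-16; adjusted p = 0.378 with an estimated correlation). Of 41 G2/M genes, 1 rose and 18 fell (1 and 19 adjusted over the list alone), CCNF by -1.39 and CDC20 by -1.27 (adjusted p = 9.31e-05; adjusted p = 0.511 with an estimated correlation).

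**Figure D4:**
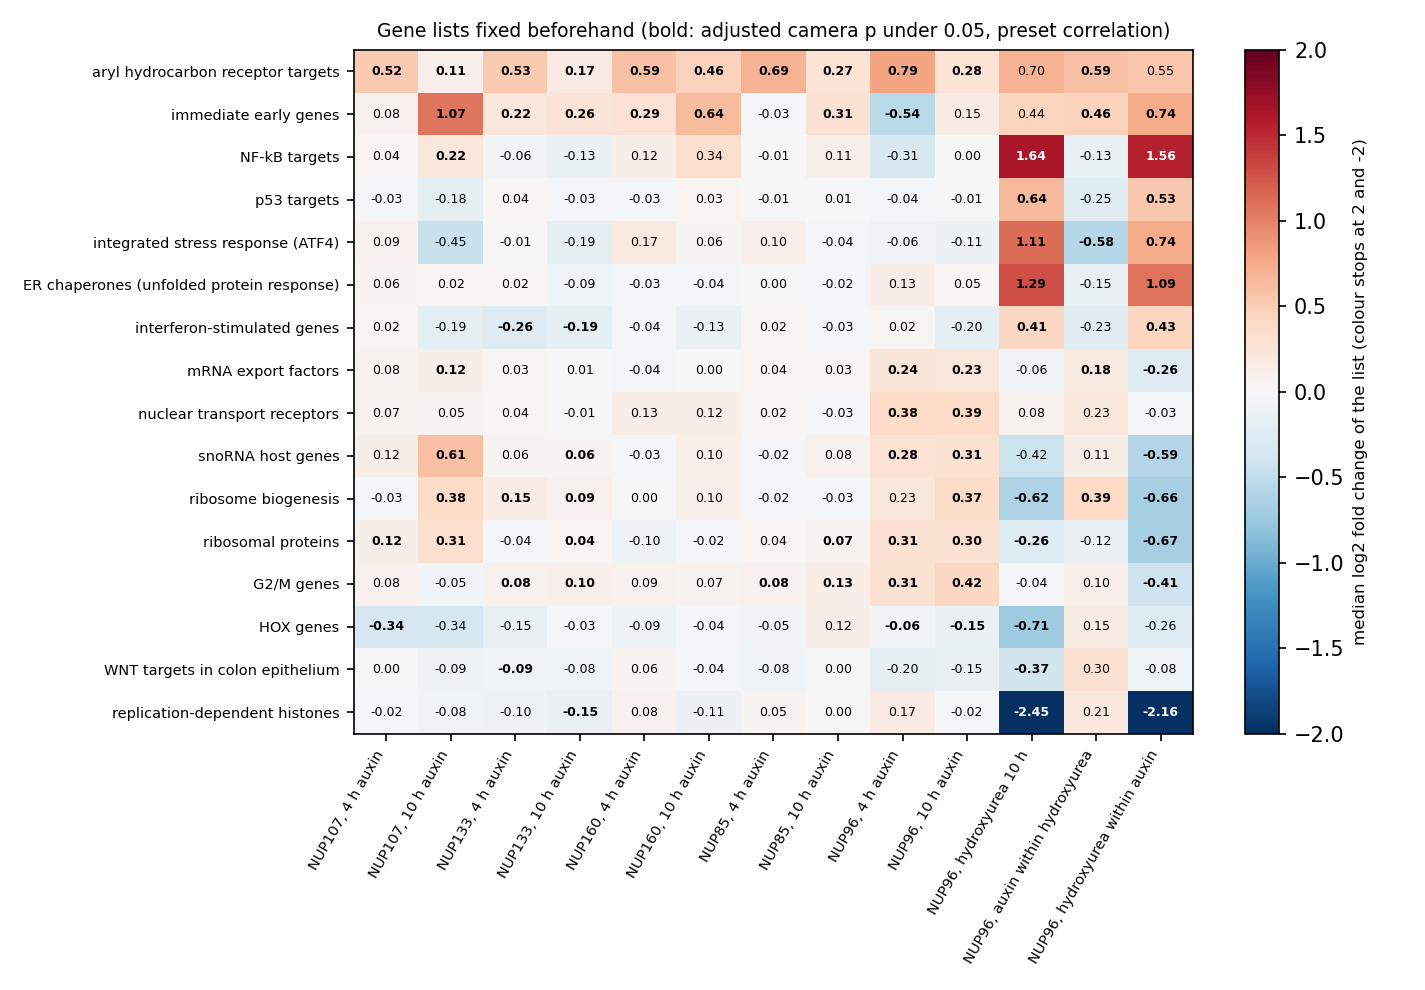
Median log2 fold change of 16 gene lists in 13 comparisons, in colour from blue (lower) to red (higher) with the scale ending at 2 in each direction; bold numbers mark an adjusted camera p under 0.05 with the preset correlation. The lowest printed histone medians are -2.45 with hydroxyurea and -2.16 with hydroxyurea added to auxin.

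The effect of auxin with hydroxyurea was compared with its effect without, and 21 genes differed, 9 higher and 12 lower with hydroxyurea, while 2834 had an unadjusted p under 0.05. ZBTB12 (difference of log2 fold changes 2.16 ± 0.46), MYPOP (1.94) and SOX9 (1.67), a transcription factor of intestinal crypts, were higher, each at an adjusted p of 0.0421. TM4SF19-TCTEX1D2 (-2.04, adjusted p = 0.0421) and RHEBL1 (-1.93, adjusted p = 0.0104) were lower. None of the 5 was called without hydroxyurea replicate 2 (adjusted p = 0.142, 0.0963, 0.102, 0.143 and 0.0698 in the order named). The same held without hydroxyurea replicate 3 (0.0671, 0.104, 0.111, 0.141 and 0.0626) and without replicate 2 of both treatments (0.102, 0.0599, 0.102, 0.109 and 0.0545). The first 4 were not called without auxin replicate 3, replicate 1 of both treatments or untreated replicate 2 either, and without the last ZBTB12 stood at 1.372, MYPOP at 1.274 and SOX9 at 0.645. Each single library left out moved the count by over 1.5 times. It was 1223, 13 and 1002 without untreated replicates 1, 2 and 3, 804, 2 and 3 without the hydroxyurea libraries, 10, 12 and 13 without the auxin libraries and 5, 6 and 95 without the libraries with both, each in the order of the replicate numbers. With the DESeq2 size factors the split was 16 higher and 13 lower, with DESeq2 238 and 70, and without the low-count filter 352 and 187. Replicate numbers paired in both auxin comparisons behind this difference. With a replicate block within each line edgeR called 2 genes, both lower, and none of the 5 named ones (adjusted p = 0.119, 0.0825, 0.119, 0.119 and 0.0751 in the order named). A fit of this line's own libraries called 0 genes with edgeR, with 787 at an unadjusted p under 0.05, and DESeq2 over all libraries called 308.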

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

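The tests of exon number, of the immediate early genes by exon number and of the receptor targets were chosen only after the result was seen. So were those on the NUP133 and NUP85 lines. The splits of the libraries were chosen before. The matched test on GC content, length and expression and the test without NUP96 untreated replicate 2 were chosen before their own outcomes were seen. Both followed the exon pattern they test, which had been found in these data.

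Each result in this paragraph stands here because the test of the difference between groups passed its threshold. The NUP107 line's 10 h response differed from the mean of the other lines for 2847 genes, with GDF15 at 2.56 and KLHL23 at -2.48 (difference of log2 fold changes). The NUP133 response differed for 934 genes, with NORAD at 1.8 and TXNIP at -1.65, the latter at -0.835 (adjusted p = 0.312) without NUP133 untreated replicate 3. The NUP85 response differed for 556 genes, with F2R at 1.68 and STAM-AS1 at -1.27, the latter at -1.07 (adjusted p = 0.158) without NUP85 untreated replicate 2. The NUP96 response differed for 1987 genes, with TPM2 at 2.21 (3.73 without untreated replicate 1, and 1.52 with adjusted p = 0.0806 without untreated replicate 3) and CTXN1 at -3.38 (-0.215 without untreated replicate 2). The NUP160 response differed for 4 genes. In the NUP96 line the auxin effect with hydroxyurea differed from that without for 21 genes, with ZBTB12 at 2.16 and TM4SF19-TCTEX1D2 at -2.04, neither called without untreated replicate 2 or with a replicate block within each line (adjusted p = 0.119 for both).

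Intron-poor genes lay lower than others after auxin in the NUP107, NUP160 and NUP96 lines. Of 328 genes with 1 exon, 161, 77 and 196 fell at 10 h in these lines, and 14, 5 and 11 rose. The smallest gap of the 3 lines between the median of genes with 1 exon and that of genes with 9 or more was -0.423 on the log2 scale. The matched difference was also below 0 in the NUP85 line at 10 h (-0.093 ± 0.021). The SDs of matched differences are those of the treated libraries and leave out the spread of the untreated ones. With hydroxyurea alone in the NUP96 line the matched difference was -0.346 ± 0.031 (-0.303 without untreated replicate 2), but the set did not pass with an estimated correlation (adjusted p = 0.12). With auxin added to hydroxyurea it was -0.780 ± 0.1 (adjusted p = 1.76e-05 with an estimated correlation). Bias by GC content, length or expression is argued against by the matched comparison, whose smallest difference was -0.378, and the shallow NUP96 untreated replicate 2 by -0.928 in the NUP96 line without it. A general fall of transcription, seen first in short-lived mRNAs, cannot be told apart in any of the 3 lines. In the NUP107 and NUP160 lines the lower median of the spliced immediate early genes at 10 h was 0.615, but induction by stress can hide a fall in these genes, and their list did not pass with an estimated correlation (adjusted p = 0.28 and 0.386). In the NUP96 line that median was -0.293 at 4 h and 0.219 at 10 h. A hypothesis left open is that mRNAs of intron-poor genes may depend more on the Y-complex, since spliced mRNAs are loaded with export factors during splicing. The 5 immediate early genes with 1 exon went both ways against the 27 spliced ones. Their medians were 0.911 beside 1.092 in the NUP107 line and 0.664 beside 0.615 in the NUP160 line at 10 h, but -1.147 beside 0.219 in the NUP96 line. At 4 h they were -0.388 beside 0.216, -0.006 beside 0.325 and -1.581 beside -0.293 in the same order. Export, transcription and decay were not measured separately.

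The list of aryl hydrocarbon receptor targets shifted up at 4 h in all 5 lines, and the lower CYP1A1 log2 fold change of the NUP133 and NUP85 lines was 5.49. Besides CYP1A1 and CYP1B1, between 1 (NUP85) and 4 (NUP96) of the other 9 targets rose in a line. Reads shared between CYP1A1, CYP1B1 and overlapping genes are argued against, because without these 2 genes the list still passed in every line, with a largest p of 0.000115 by camera with an estimated correlation. Loss of the tagged protein cannot be told apart from an action of auxin itself, an indole, because no untagged line with auxin was analysed here. A candidate explanation is activation of the receptor by auxin, which would leave the rise alike in lines with many and with few other changes. The targets were divided on this. At 4 h CYP1A1 and CYP1B1 in the NUP133 and NUP85 lines lay within the range of the other lines. TIPARP (1.01 and 0.87) and AHRR (0.59 and 0.69) lay below them, though the TIPARP differences were not called (adjusted p = 0.638 and 0.722). TIPARP can also move apart from the other targets. With hydroxyurea and no auxin in the NUP96 line it rose by 1.42, while CYP1A1 (-1.03), CYP1B1 (-1.37) and AHRR (-0.83) fell. At 10 h CYP1A1 was lower in the NUP133 and NUP85 lines too (1.85 and 1.52, against 2.13 to 3.73). For AHRR, and for CYP1A1 at 10 h, no test of the difference between lines is given here.

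Few genes were called in the NUP133 and NUP85 lines. For the 4 h libraries, untreated cells or labels exchanged within a line are argued against by CYP1A1. Its lowest 4 h library lay at least 20 times above the highest untreated library of its line in both. CYP1A1 rose at 4 h in every line, so it cannot show whether libraries were exchanged between lines. Nor does this check cover the 10 h libraries. There the lowest library stood at 9.09 CPM against a highest untreated one of 7.77 in the NUP133 line, and at 7.15 against 3.26 in the NUP85 line. The test of the difference itself found at least 556 genes in each of these lines. For those genes, a response as large as in the other lines, hidden by spread or depth, is argued against. That test uses the spread pooled over all groups, so it does not account for a larger spread within these lines. It also does not cover a response in other genes. Whether the tagged protein was lost to the same extent in every line stays open, because RNA does not measure it, and these subunits may also be needed less within 10 h.

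Other splits of the same libraries were counted for each result. For 3 libraries against 3 there are 10 splits, too few for a share under 0.05, with 1 of them reaching the real count in each comparison but the NUP133 line at 10 h, where all 10 do because that count was 0 with edgeR. In fits of the compared libraries alone at 10 h, the real split gave 12352 genes in the NUP107 line, 1413 in the NUP160 line, 77 in the NUP85 line, 186 in the NUP96 line and 0 in the NUP133 line, and the highest other split 0, 0, 2, 0 and 0. At 4 h it gave 4569, 52, 44, 1 and 3 in the same order, with 0 in each highest other split. For hydroxyurea it gave 587, for auxin added to hydroxyurea 1163 and for hydroxyurea added to auxin 5863, again with 0 in the highest other split. For the difference between auxin effects with and without hydroxyurea, the real split called 0 genes with edgeR in this fit, so that all 70 of 70 splits give as many and the count decides nothing about chance.

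The 100 splits drawn for each line against the others shuffled the untreated and 10 h labels in all 5 lines at once. Such splits ask whether any line responded, and not whether 1 line responded as the others did. Only 1 split, the real one, was as large for the NUP133 line (756 genes, highest other 0) and the NUP85 line (388 genes, highest other 0). The same held for the genes shared by all 5 lines (3 genes, highest other 0). There a split that mixes the labels of any 1 line is unlikely to match, so that count decides little. Chance cannot be excluded by this count for the NUP107 line (12 splits as large, 2373 genes, highest other 6490), the NUP160 line (7 splits, 1 gene, highest other 1683) and the NUP96 line (13 splits, 1266 genes, highest other 6126). Splits that keep or exchange a line's own labels keep its response. They are too frequent for a share under 0.05 in a line with a large response. Splits with several times the real count do not by themselves mark a structure of the libraries. Shuffling the other lines' labels also takes their response out of the comparison. All 12 for NUP107, the real split among them, kept or exchanged that line's own labels, and the highest count among the 88 splits that mixed the NUP107 labels was 0. For NUP160 and NUP96 the highest counts with own labels mixed were 298 and 1872.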

How the results depend on the processing

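All alternatives were planned except the 2-group replicate block, leaving out NUP96 untreated replicate 2 and NUP160 untreated replicate 3 together, the genes counted in every line, and the exon analysis under hydroxyurea without NUP96 untreated replicate 2, which were chosen only after the results were seen. Of the values of named genes under single libraries left out, 8208 kept direction and side of the threshold, 947 lost the call, 23 gained one and 8 reversed. No scaling moved the median of all genes by over 0.1 on the log2 scale (largest -0.080, with the 20 most abundant genes removed under hydroxyurea). Every scaling used assumes that most genes do not change, so their agreement cannot show whether total mRNA changed. No external reference entered the scaling, and rises and falls are relative to the other genes. With an estimated correlation, 301 list results kept their call or lack of one and 91 lost it. Where a cause is not given, the cause was not tested. The standard error of a log2 fold change near 0.24 limits what 3 libraries can show: in the simulation of the NUP85 line at 10 h, 36% of 1.5-fold changes were recovered.

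With a minimum of 2-fold added, which by construction calls fewer genes, the counts at 10 h were 3296 for NUP107, 653 for NUP160 and 2919 for NUP96. At 4 h they were 418 for NUP107, 5 for NUP133, 45 for NUP160 and 1166 for NUP96. For hydroxyurea the count was 4928, for auxin added to hydroxyurea 1690 and for hydroxyurea added to auxin 3151. For a line against the others they were 1129 for NUP107, 353 for NUP133, 1 for NUP160, 165 for NUP85 and 990 for NUP96, and 1 gene was shared by all 5 lines. In the NUP160 line at 10 h the majority turned, to 342 higher and 311 lower.

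With DESeq2 the counts were 21 for NUP133 and 19 for NUP85 at 10 h, 20 for NUP133, 246 for NUP160 and 12 for NUP85 at 4 h, 308 for the difference between auxin effects with and without hydroxyurea, and 16 for NUP160 and 858 for NUP85 against the other lines. Without the low-count filter, which adds genes to the test, they were 36 for NUP133 and 24 for NUP85 at 10 h, 75 and 10 at 4 h, 539 for the difference between auxin effects, 38 for NUP160 against the others and 8 shared by 5 lines. The 75 for NUP133 at 4 h were 20 higher and 55 lower. With DESeq2 size factors, and with the 20 most abundant genes removed, the NUP160 line differed from the others for 1 gene, a higher one, in place of 3 higher and 1 lower. With the size factors the difference between auxin effects split into 16 higher and 13 lower, against 9 and 12.

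With only the libraries of the compared lines, the spread is estimated from those libraries alone. They are fewer, and their spread can differ from the one pooled over all groups. The counts were then 12204 for NUP107, 0 for NUP133, 2814 for NUP160, 129 for NUP85 and 2235 for NUP96 at 10 h, and 4649, 5, 243, 79 and 162 at 4 h. They were 5717 for hydroxyurea, 1054 for auxin added to hydroxyurea, 2705 for hydroxyurea added to auxin, 0 for the difference between auxin effects, 12 for NUP160 and 875 for NUP85 against the others, and 0 shared by 5 lines. The 0 for NUP133 is edgeR's, with 620 genes at an unadjusted p under 0.05 there and 21 genes called by DESeq2 over all libraries. The 0 for the difference between auxin effects had 787 such genes, and DESeq2 called 308.

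Replicate numbers did not pair the libraries in the other comparisons. A replicate block within each line gave 5 genes for NUP133 at 10 h, 2 for the difference between auxin effects and 0 for NUP160 against the others (1217 at an unadjusted p under 0.05 with edgeR; DESeq2 without the block called 16). The 2-group replicate block, over the groups whose numbers paired, gave 8383 genes for NUP96 at 10 h and 5203 for auxin added to hydroxyurea, and changed the calls of no named genes there but NUP107, NUP133 and NUP160.

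Without NUP96 untreated replicate 2 and NUP160 untreated replicate 3, the counts that moved by over 1.5 times were 23 for NUP133 and 22 for NUP85 at 10 h, 1547 for NUP107, 21 for NUP133, 9 for NUP85 and 1049 for NUP96 at 4 h, and 1594 for NUP133, 1050 for NUP85 and 944 for NUP96 against the others. Values that reversed did so both without NUP96 untreated replicate 2 alone and without both libraries. In the NUP96 line at 10 h TGFB1 went from -0.956 to 0.178 and 0.176, and its lowest value without another single library was -1.319. At 4 h POM121 went from -1.14 to 0.02 and 0.029 (lowest -1.534), and POM121C from -1.21 to 0.393 and 0.402 (lowest -1.649). In the NUP96 line against the others GAL3ST2 went from -3.002 to 0.952 and 0.922 (lowest -3.59), ANP32B from -2.98 to 0.422 and 0.457 (lowest -3.524), POM121 from -1.11 to 0.057 and 0.068 (lowest -1.509), SOX9 from -0.886 to 0.14 and 0.156 (lowest -1.208), and TGFB1 from -1.11 to 0.026 and 0.008 (lowest -1.473).

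Without single libraries the counts ranged from 5621 to 5854 for NUP107, 1 to 5 for NUP133, 1001 to 1525 for NUP160, 1 to 8 for NUP85 and 5211 to 8680 for NUP96 at 10 h. At 4 h they ranged from 595 to 780, 1 to 22, 67 to 202, 1 to 3 and 944 to 6230 in the same order. They ranged from 8433 to 10627 for hydroxyurea, 3222 to 5698 for auxin added to it, 5577 to 8340 for hydroxyurea added to auxin and 2 to 1223 for the difference between auxin effects. Against the other lines they ranged from 1960 to 3939 for NUP107, 527 to 1480 for NUP133, 0 to 18 for NUP160, 279 to 1012 for NUP85 and 790 to 5161 for NUP96, and 1 to 3 genes were shared by all 5 lines.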

Other observations

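The paragraphs below report values; the lists were planned, and the comparison of lines at 4 h was chosen only after the results were seen.

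With hydroxyurea in the NUP96 line, further lists held called genes, and none of them passed camera's test with an estimated correlation. Of 20 TGF-beta and mesenchymal genes, 10 rose and 5 fell (11 and 5 adjusted over the list alone), with the inhibitors of differentiation ID1 (log2 fold change -3.17) and ID3 (-2.63) among the falls (list adjusted p = 0.288). Host genes of small nucleolar RNAs gave 3 rises and 11 falls among 20 (4 and 11 adjusted over the list alone), SNHG25 by -1.38 and SNHG7 by -1.02 among them (list adjusted p = 0.111). Among 24 interferon-stimulated genes, 10 rose and 2 fell (the same adjusted over the list alone), OASL by 2.67 and STAT2 by 1.08 (adjusted p = 0.0311; adjusted p = 0.55 with an estimated correlation). Of 16 intestinal differentiation markers, 7 rose and 2 fell (the same adjusted over the list alone), with the carbonic anhydrase CA2 at 1.44 and the homeobox factor CDX2 at -2.79 (-3.59 without hydroxyurea replicate 1; list adjusted p = 0.418). Among 14 abundant structural nuclear RNAs, 3 rose, MALAT1 by 2.56 among them, and 4 fell (the same adjusted over the list alone; list adjusted p = 0.844). Of 18 heat shock genes, 4 rose and 3 fell (2 and 3 adjusted over the list alone), HSPA6 by 3.09 and HSPB1 by -2.01 (list adjusted p = 0.774). Among 22 hypoxia targets, 4 rose and 4 fell (the same adjusted over the list alone), VEGFA by 1.76 among the rises (list adjusted p = 0.522).

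Of 24 cholesterol synthesis genes, 2 rose and 5 fell in the NUP107 line at 10 h (4 and 6 adjusted over the list alone; list adjusted p = 0.758). In the NUP133 line at 10 h the list had a median of -0.25 (adjusted p = 0.000424; adjusted p = 0.887 with an estimated correlation).

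The test of each line's 4 h effect against the mean of the other lines called 576 genes for NUP96, 159 for NUP107, 144 for NUP133, 2 for NUP85 and 0 for NUP160 with edgeR; DESeq2 was not run on it. ARRDC4 stood above the other lines in NUP96 (difference of log2 fold changes 1.29, adjusted p = 0.000835) and NUP107 (0.89, adjusted p = 0.0201) and below them in NUP133 (-1.30, adjusted p = 0.000219). TXNIP stood above them in NUP96 (1.62, adjusted p = 0.0404) and below them in NUP133 (-2.42, adjusted p = 0.00252).

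HIST1H3PS1, called in all 5 lines at 10 h, and MT-RNR1, called in the NUP160 line, can share reads with copies elsewhere in the genome, which was not tested here. MT-RNR1 had a mean of 0 CPM in every group outside the NUP160 line, in line with the different feature set of those libraries.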
